A study of Arabidopsis thaliana with 6 samples.

How the data were processed

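RNA was sequenced from whole Arabidopsis thaliana seedlings of 2 genotypes, with 3 libraries per genotype, 6 in all. Per the labels, RNA was extracted with a column kit and sequenced with the Illumina mRNA protocol. The labels give the genotypes as the fhy1-1 mutant and the same mutant carrying GFP-FHY1 behind the 35S promoter, and call the 3 samples of each genotype biological replicates. The series' files used here are 1 gene-level comparison of the genotypes. Per the file headers it has the layout of a Cuffdiff gene table, and the submitters' processing notes name Bowtie and TAIR10. Tool versions, strand handling, filters and the dispersion setting of the test are not given in the sources used here.

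The headers of the value columns name no unit. The values are read here as FPKM (fragments per kilobase of transcript, scaled to the total of mapped fragments) from the Cuffdiff layout. The authors' deposited table gives 1 such value per gene and genotype, combined over the replicates. The table therefore shows no spread between replicates, and no SD can be given for any gene. The authors' deposited test statistic is a score of opposite sign to the fold change, and the authors' deposited p-value equals the two-sided normal tail of that score to within 2.75e-06. The authors' deposited q-value equals a Benjamini-Hochberg adjustment over the tested genes to within 1.82e-06. The authors' deposited log2 fold change column holds a placeholder in place of infinity for 1730 genes, so fold changes were recomputed from the FPKM values, which matched the column to within 1.46e-05 wherever both values were above 0. The number of reads per library is unknown from FPKM, so no counting interval is given.

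The table lists 33557 genes. The authors tested 23937 of them; 9568 were not tested, 33 had too little data, 17 failed and 2 had too much. Of all identifiers, 97.8% were found in the TAIR10.1 RefSeq annotation, which was used for gene names, product descriptions and transcript lengths. Coordinates are those of the table (TAIR10), written from 1. Only 39.0% of gene starts equalled those of the RefSeq annotation, so coordinates of the annotation were not used. In the table, 4249 genes overlap the locus of another gene, and reads of such genes cannot be told apart where strand is unknown.

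A gene was called when the authors' q was below 0.05, and its direction was taken from the FPKM values. This design, 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists hold 447 members other than those of the chloroplast and mitochondrial lists. The reference gave the listed symbol for 430 members and spelled or named the remaining 17 otherwise, and no member was left out. For each list with a tested member, Fisher's exact test (two-sided) compared the share of members called higher, and called lower, with all other tested genes. Calls in either direction together were tested likewise, and each test had Benjamini-Hochberg adjustment over 23 lists. Unless said otherwise, a list is said to pass when it held more higher calls or more lower calls than expected. Each list's median log2 fold change was also placed among the medians of 10000 random lists matched on mean FPKM in 20 bins. Members of a list are not independent of each other, so these p-values describe the table. Calls on neighbouring genes were compared with 10000 permutations of the calls over the tested genes (one-sided). Windows of 1 Mb were tested with Fisher's exact test (one-sided). The named genes are FHY1, the 8 called genes with the largest fold in each direction at a mean of at least 5 FPKM with both values above 0, and up to 4 called members of each list at a mean of at least 1 FPKM, or the 2 members with the highest mean where none was called. The text names part of that set, and any other gene is said to have been chosen after its values were seen.

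The alternatives were a q below 0.01, a log2 fold change of at least 1, a minimum of 1 FPKM in either genotype, Bonferroni adjustment, a pseudocount of 1 with a change of at least 0.58, centring on the median, leaving out overlapping loci, and cameraPR on the ranks of the authors' statistic with preset correlations of 0.01 and 0.05. No correlation between genes could be estimated without values per library. After the data were examined, 2 kinds of alternative were added. The error implied by the fold change and statistic was widened by a replicate spread of 10% or 20% (coefficient of variation, 3 libraries per genotype) and the genes were retested, which leaves genes with a value at 0 uncalled. Fold changes were also centred and retested with the implied error.

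The list, neighbour and window tests were tested on simulated data, with calls placed at random over the 23937 tested genes at the observed rates. With 60% of members called in 3 chosen lists, all 300 such lists over 100 runs were found, and 18 of 2000 other lists were called. With 200 added pairs of like neighbours, 20 of 20 runs were called, against 1 of 20 without them. A window with 50% of genes called was found in 20 of 20 runs, and 1 other window was called over those runs. Unchanged genes simulated with a replicate spread of 10% gave a mean of 2286 calls among 23355 genes when tested with the implied error alone, and 0.05 when the spread was included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.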

Results

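Transcript levels were measured by RNA sequencing in 4-day-old Arabidopsis seedlings, which the labels describe by a light code of 4 days (D) and 3 h of far-red (FR). FHY1 is a chaperone that carries the far-red photoreceptor phytochrome A into the nucleus. The fhy1-1 mutant lacks its normal function, and the second genotype is fhy1-1 carrying a GFP-FHY1 fusion under the strong 35S promoter, with 3 libraries of each. The comparison asks which transcripts differ when GFP-FHY1 is present. The samples include no wild type and no seedlings without far-red. Restored FHY1 function therefore cannot be told apart from an excess of FHY1, nor a response to far-red from a standing difference between the lines. The authors' deposited table holds 1 FPKM value per gene and genotype, so values below have no SD, the depth of each library is unknown, and a call means that the authors' q was below 0.05.

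FHY1 itself (AT2G37678, chromosome 2, 15801465 to 15802793, TAIR10) was the check on the labels. Its transcript was at 18.9 FPKM in fhy1-1 and 195.9 FPKM in the GFP-FHY1 line, 10.3-fold higher (log2 fold change 3.37), with q listed as 0 in the authors' deposited table. FPKM over this gene model cannot separate the mutant transcript from that of the transgene.

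Photosynthesis genes and many genes of pigment synthesis and light signalling were higher in the GFP-FHY1 line, and seed storage transcripts were lower. The authors' deposited table called 2375 genes higher and 3089 lower, together 22.8% of 23937 tested genes. The larger changes were mostly increases: 508 called genes were at least 2-fold higher and 114 at least 2-fold lower, and 120 were at least 4-fold higher against 9 lower. LHCB1.4 (AT2G34430, chromosome 2, 14524756 to 14525763), which encodes a light-harvesting chlorophyll a/b-binding protein, rose 46.1-fold, from 1.98 to 91.3 FPKM. FBA5, a fructose-bisphosphate aldolase, rose 30.9-fold to 11.2 FPKM, the lipid-transfer family gene AT5G48490 28.4-fold to 43.8 FPKM, and MSRB6, a methionine sulfoxide reductase, 18.8-fold to 31.0 FPKM. Among the genes that fell, the seed albumin gene SESA5 (AT5G54740, chromosome 5, 22238358 to 22239187) went from 39.8 to 4.95 FPKM, 8.05-fold lower. GRF7, a growth-regulating factor, fell 3.61-fold from 68.8 FPKM, SEN1, a gene known from senescence and darkness, from 103.7 to 28.8 FPKM, and the copper transporter gene COPT3 3.36-fold from 13.3 FPKM.

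Most calls were small. In the authors' deposited table, 4078 called genes, 74.7% of those with both values above 0, differed by less than 1.5-fold, and the median log2 fold change was 0.49 for genes called higher and -0.27 for those called lower. The number of such calls rests on the error of the authors' test: with a replicate spread of 10% added to it the calls became 1193 higher and 599 lower, and with 20% they became 577 and 93. The split between directions also depended on scaling. The median tested gene at 1 FPKM or more was at -0.05 on the log2 scale, and centring on it with a new test gave 2887 higher and 2215 lower, 56.6% higher against 43.5% as deposited. The ribosomal RNA locus gene AT2G01021 held 28.6% of the FPKM sum in fhy1-1 and 38.0% in the GFP-FHY1 line, and was chosen after its values were seen.

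Light-harvesting and photosystem genes rose as a group. All 20 tested light-harvesting genes were called higher in the authors' deposited table, with a median log2 fold change of 1.66 (Fisher's exact test, adjusted p = 9.15e-20). LHCB1.1 rose from 37.6 to 452.6 FPKM, LHCB2.3 from 33.9 to 255.3 FPKM and LHCB2.2 from 69.0 to 449.6 FPKM. All 26 nuclear photosystem and Rubisco small subunit genes were also called higher (median 1.06, adjusted p = 1.66e-25), among them PSBQ2, 3.84-fold, PSBO2, 3.80-fold, PSAK, 3.25-fold, and PSAN, 3.24-fold. Adjusted over the list alone, the counts were again 20 and 26. Members of the LHCB1, LHCB2 and Rubisco small subunit families are near-identical, and the share of reads given to each copy is uncertain. All 279 genes of the chloroplast and mitochondrial genomes were listed at 0 and untested, so the organelle-encoded lists gave no comparison.

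**Figure D1:**
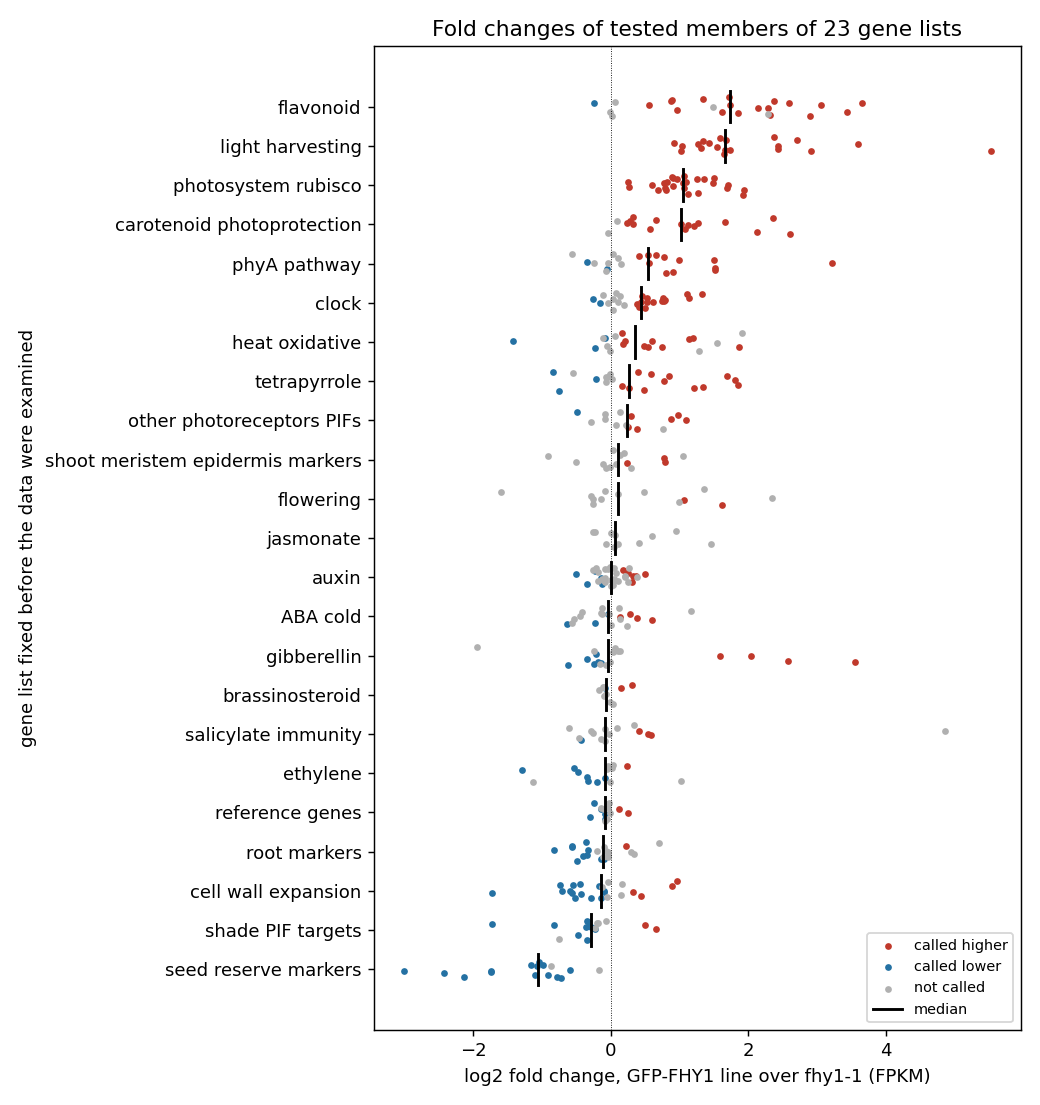
Each point is 1 tested gene with values above 0 in both genotypes, placed by its log2 fold change of FPKM (GFP-FHY1 line over fhy1-1, horizontal axis) within its gene list (vertical axis); colours mark genes called higher, called lower or not called by the authors, and black bars are list medians. The medians run from -1.06 for seed reserve markers to 1.73 for flavonoid genes.

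Many pigment genes were called higher. In the chlorophyll and haem (tetrapyrrole) list, 12 of 21 genes were called higher and 3 lower in the authors' deposited table (median 0.26, adjusted p = 3.63e-07 for higher). CHLH, a subunit of the magnesium chelatase, rose 3.59-fold, its activator GUN4 3.51-fold, HEMA1, which encodes glutamyl-tRNA reductase, 3.24-fold, and CAO, chlorophyllide a oxygenase, 2.52-fold. The adjusted p for this list was 0.0700 in cameraPR with a preset correlation of 0.05. Of 25 flavonoid genes, 18 were called higher and 1 lower (median 1.73, adjusted p = 1.14e-12). They included the anthocyanin regulator PAP1 (12.6-fold, to 10.7 FPKM), the anthocyanin transport gene GSTF12 (10.8-fold, to 4.06 FPKM), 4CL3 (4.95-fold) and CHIL (4.89-fold). Carotenoid and photoprotection genes followed, with 15 of 17 called higher and none lower (median 1.02, adjusted p = 7.34e-13). ELIP2 and ELIP1, early light-induced proteins, reached 1205 and 1328 FPKM, 6.08-fold and 4.34-fold higher, the plastid sigma factor gene SIG5 rose 5.10-fold, and PSY, phytoene synthase, 3.15-fold. Adjusted over the list alone, 12 tetrapyrrole, 21 flavonoid and 15 carotenoid genes were higher, and 4, 1 and 0 lower.

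Among light signalling genes, 12 of 21 members of the phytochrome A pathway were called higher and 2 lower in the authors' deposited table (median 0.54, adjusted p = 3.63e-07). BBX25, a B-box regulator, rose 9.29-fold from 3.14 FPKM, HYH, a close relative of HY5, 2.86-fold, and SPA4 and SPA3, partners of the COP1 ubiquitin ligase, 2.85-fold and 2.83-fold. The loci of BBX25, SPA3 and SPA4, and that of PHOT2 named next, overlap other genes in the table. Of 14 other photoreceptors and PIF factors, 6 were called higher and 1 lower (adjusted p = 0.00360). PHOT2 rose 2.14-fold, PIF4 1.96-fold and PIF5 1.84-fold, and PHOT1 fell from 88.1 to 62.8 FPKM. That list had an adjusted p of 0.0535 in cameraPR with a preset correlation of 0.05. In the circadian clock list, 15 of 25 genes were called higher and 2 lower (median 0.45, adjusted p = 4.88e-09), with PRR9 2.52-fold and RVE1 2.15-fold higher and RVE7 up from 17.3 to 38.1 FPKM. Adjusted over the list alone, the higher counts were 12, 8 and 15, and the lower counts 3, 1 and 2. With a replicate spread of 20% added, the clock and other photoreceptor lists no longer passed the test (adjusted p = 0.0621 and 0.111), nor did the other photoreceptor list when at least a 2-fold change was required (adjusted p = 0.543).

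Seed reserve transcripts fell. In the authors' deposited table, 14 of 16 tested markers of seed storage, oil bodies and reserve use were called lower and none higher (median -1.06, adjusted p = 7.40e-10), and 15 were lower adjusted over the list alone. The cruciferin gene CRA1 fell 5.34-fold from 32.5 FPKM, PAP85 4.39-fold from 4.14 FPKM and SESA4 3.34-fold from 1.85 FPKM. The SESA genes are similar in sequence, so their separate values are uncertain.

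The cell wall, shade, ethylene and root marker lists passed the test for lower calls. Among random lists matched on FPKM, the median of the shade list lay at percentile 0, but those of the cell wall, root and ethylene lists lay at percentiles 7.11, 18.7 and 40.5. Of the remaining lists that passed, seed reserve markers lay at percentile 0 and the 9 lists with higher calls at 99.92 or above. Of 23 expansin and xyloglucan-modifying genes, 14 were called lower and 4 higher in the authors' deposited table (adjusted p = 1.03e-06 for lower). XTH15 fell from 478.9 to 145.1 FPKM and XTH5 1.66-fold, while XTH7 rose 1.94-fold and the expansin gene EXPA1 1.85-fold. Among 17 shade-avoidance and PIF target genes, 10 were called lower and 2 higher (median -0.28, adjusted p = 7.92e-05). PAR1 fell 1.77-fold, and HFR1, which also belongs to the phytochrome A pathway, and YUC8 rose 1.57-fold and 1.41-fold. Of 15 ethylene and apical hook genes, 7 were called lower and 1 higher (adjusted p = 0.00679). HLS1, needed for the apical hook, fell 2.44-fold, ACO1 1.45-fold and ACS5 1.39-fold. The adjusted p of the ethylene list was 0.0551 and 0.128 in cameraPR with preset correlations of 0.01 and 0.05. Root markers were called lower in 10 of 21 cases and higher in 1 (median -0.11, adjusted p = 6.58e-04), with PHT1-1 1.48-fold, GL2 1.48-fold and RHS19 1.41-fold lower. The locus of GL2 overlaps another gene. Adjusted over the list alone, the lower counts of these 4 lists were 14, 11, 8 and 11. None of the 4 passed the test with at least a 2-fold change required or with a replicate spread of 20% added, where each had at most 1 lower call. With a pseudocount of 1 and a change of at least 0.58, the shade list (2 lower, adjusted p = 0.106), the ethylene list (1 lower, adjusted p = 0.683) and the root markers (0 lower) no longer passed either, and the cell wall list did (3 lower, adjusted p = 0.0208).

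In the heat and oxidative stress list, 10 of 21 genes were called higher and 3 lower in the authors' deposited table (adjusted p = 3.29e-05 for higher). HSFA2 rose 2.29-fold and HSP70 from 11.0 to 24.2 FPKM, and HSP22 fell 2.67-fold. That enrichment was lost with a replicate spread of 20% added. The gibberellin list did not pass for higher or for lower calls as deposited, with 4 of 20 genes higher and 6 lower. Calls in either direction together were more than expected (Fisher's exact test, adjusted p = 0.0126). The list held large increases: the catabolic gene GA2OX1 rose 11.8-fold to 5.34 FPKM, GASA6 5.97-fold to 84.4 FPKM, the biosynthetic gene GA3OX2 4.12-fold to 2.67 FPKM and GA2OX2 2.99-fold to 12.4 FPKM. It passed for higher calls when at least a 2-fold change was required, with Bonferroni adjustment, with a pseudocount of 1, and with a replicate spread of 10% or 20% added. No enrichment of higher or of lower calls passed as deposited for auxin (6 of 37 higher, 5 lower), abscisic acid and cold (4 and 3 of 21), brassinosteroid (2 and 1 of 10), salicylate (3 and 1 of 15), flowering (2 and 0 of 14), shoot meristem and stomatal markers (3 and 0 of 14) or reference genes (2 and 5 of 14). For the reference genes, calls in either direction together were more than expected (Fisher's exact test, adjusted p = 0.0342). None of 12 jasmonate genes was called, and MYC2 stood at 44.7 and 45.1 FPKM in fhy1-1 and the GFP-FHY1 line. Of the reference genes, GAPC2 fell 1.23-fold and UBQ10 rose 1.18-fold. Adjusted over the list alone, the gibberellin counts were 4 higher and 7 lower, those of heat and oxidative stress 12 and 3, auxin 7 and 5, and reference genes 2 and 6. The other lists of this paragraph kept their numbers of calls.

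Calls were not scattered evenly along the chromosomes. In the authors' deposited table, 829 pairs of adjacent tested genes were called in the same direction, against a mean of 633.7 and a range of 555 to 719 in 10000 permutations (p = 0.0001, the smallest they can give). Without pairs whose loci overlap there were 766, against 502 to 679. The permutations ignored FPKM and gene copies lying side by side, so neither was separated from this excess. No window of 1 Mb passed the test for more calls. The smallest adjusted p over 121 windows was 0.0805, for chromosome 4 from 16000001 to 17000000, where 83 of 263 tested genes were called.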

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

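The alternatives with a replicate spread added and the centring with a new test were chosen after seeing the data. Against 2375 genes higher and 3089 lower, the counts were 508 and 114 with at least a 2-fold change, 1268 and 1258 with Bonferroni adjustment, 837 and 255 with a pseudocount of 1 and a change of at least 0.58, 1193 and 599 with a replicate spread of 10% added, and 577 and 93 with 20%. Stricter thresholds or wider errors lower such counts by construction. The number of lists that passed the test was 14 and became 8 with a spread of 20%, and stayed between 10 and 16 under the other alternatives. FHY1 stayed called under each, with log2 fold changes from 3.3 to 3.42. The ratio of like neighbouring pairs to the permuted mean was 1.31, and 1.17 within 3 places, and no window passed at 500 kb or 2 Mb. Of the 95 other named genes, 39 lost the call with at least a 2-fold change, 30 with the pseudocount, 19 with Bonferroni adjustment, 19 with a spread of 10% and 40 with 20%, and none changed direction. The reference gene list passed for lower calls with q below 0.01, with Bonferroni adjustment and in cameraPR with a correlation of 0.01 (adjusted p = 0.0409, and 0.0617 with 0.05). No paired analysis was possible because the table gives 1 value per genotype and carries no replicate numbers. For the same reason no replicate could be left out and the libraries could not be split in other ways. Depth limits the comparison in an unknown way, since FPKM does not keep it.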

Other observations

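Peroxidase and extensin genes were among the families that passed a test for an excess of lower calls in the GFP-FHY1 line. In that line, 10 of 21 root markers were also called lower in the authors' deposited table. They included GL2 (log2 fold change -0.56), whose locus overlaps another gene, and the root hair gene RHS19 (-0.49). Tested genes were grouped by product description, which gave 231 families of at least 10 genes, a test chosen after the data were examined. Unlike the random lists, families were not matched on FPKM. The median implied error fell from 0.45 in the lowest bin of FPKM times transcript length to 0.026 in the highest. An excess or shortage of calls in a family was therefore not separated from its expression level. In the authors' deposited table, 7 families held more lower calls than expected from the remaining genes (Fisher's exact test, Benjamini-Hochberg over families, adjusted p < 0.05) and none more higher calls. Families needed identical descriptions. The light-harvesting and photosystem genes named above differ in description from each other, so the grouping did not bring them together. The lack of families with more higher calls therefore does not bear on them. The same test found fewer lower calls than expected in 6 families: pentatricopeptide repeat proteins (2 of 191, adjusted p = 4.24e-07), RING/U-box (12 of 247, 9.93e-04), tetratricopeptide repeat-like (13 of 260, 9.93e-04), protein kinases (16 of 281, 0.00180), TIR-NBS-LRR disease resistance proteins (0 of 55, 0.0173) and F-box proteins (2 of 82, 0.0274). Of 57 peroxidases, 22 were called lower and 7 higher (median log2 fold change -0.18, adjusted p = 9.24e-05). Of 14 proline-rich extensins, which are structural cell wall proteins, 10 were lower and none higher (median -0.46, adjusted p = 9.24e-05). The plant invertase/pectin methylesterase inhibitor superfamily stands under 2 product descriptions, and that name does not tell pectin methylesterases from their inhibitors. Under the first, 12 of 26 genes were lower and 2 higher (adjusted p = 0.00133). Under the second, which did not pass, 7 of 40 were lower and 3 higher (median 0.06, adjusted p = 0.671). Among 62 pectin lyase-like genes 13 were lower and 5 higher, which did not pass (adjusted p = 0.406). Of 52 aspartyl proteases 16 were lower and 1 higher (adjusted p = 0.0148), and of 10 endomembrane protein 70 genes 7 were lower and 0 higher (adjusted p = 0.00153). A ribosomal protein family (L7Ae and relatives) had 8 of 11 lower and 0 higher (adjusted p = 5.65e-04), and TCP-1 chaperonins 8 of 13 lower and 1 higher (adjusted p = 0.00153). With a replicate spread of 10% added, 4 of the 7 families with more lower calls still passed, and the other 3 did not. Those that passed were the extensins, the first invertase/pectin methylesterase inhibitor description, peroxidases and aspartyl proteases.

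The tests of the implied error and of the shoot markers were chosen after the result was seen. Most calls were below 1.5-fold. The tables argue against a scaling shift as the whole cause, since 3705 such calls were made after centring and retesting, against 4078. These totals are not of the same genes: of all 5102 calls after centring, 4590 were among the 5464 deposited calls. The tables also argue against a trend with transcript length. Its rank correlation with fold change across genes was 0.13. Again as totals, 3506 calls below 1.5-fold were made with the trend removed, against 4091 among the genes with a length and an implied error. The error implied by the authors' statistic kept falling with FPKM times transcript length, with a slope of -0.47 on log2 scales (95% bootstrap interval -0.48 to -0.47). Counting error alone gives about -0.5, and a constant replicate spread would flatten the slope. A candidate explanation for the many small calls is therefore a test whose error holds little constant replicate spread. The median implied error in the highest bin, 0.026, equals that of a replicate spread of 2.21% alone. An error larger than counting error by a fixed factor would give the same slope. The level of counting error is unknown without depth, so the slope cannot tell these apart.

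Photosynthesis transcripts were higher in the GFP-FHY1 line. Sharing of reads between near-identical copies does not account for it as a whole: the 24 members outside the multicopy families had a median log2 fold change of 1.26, from 0.78 to 2.43. A larger share of shoot tissue that raised all shoot transcripts alike does not account for the whole rise either. The interval of at least 95% coverage of the median of 10 shoot meristem and stomatal markers at 1 FPKM or more ended at 0.77. That lay below the 1.05 to 1.59 of the 46 photosynthesis list members. These markers cover the meristem and stomatal lineage only, so a larger share of other shoot tissue stays open for part or all of the rise. For the tissue the markers do cover, a contribution to part of the rise was neither shown nor excluded. Their median was 0.089, and their interval ran from -0.11 to 0.77. Root markers (10 of 21 called lower in the authors' deposited table, median -0.11 at percentile 18.7 of matched random lists) did not settle the question. Genotype is the labelled difference between the groups, and a change in tissue share could itself follow from it. By what route genotype would raise these transcripts was not tested.

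Seed storage transcripts were lower in the GFP-FHY1 line. A hypothesis written before its test was that fhy1-1 seedlings were less advanced in using seed reserves, so that other seed maturation genes would be lower too. The 36 other genes with late embryogenesis abundant, oleosin, caleosin or seed storage products had a median log2 fold change of -0.079 (interval -0.24 to 0.06). Of these, 12 were called lower and 3 higher in the authors' deposited table. The oleosin gene OLEO3 fell from 64.2 to 31.2 FPKM and the caleosin gene RD20 from 73.4 to 37.1 FPKM. The oleosin-B3-like gene AT1G13930 rose from 118.7 to 266.6 FPKM. These genes were chosen after their values were seen. The set was picked by product words, and its members were not shown to follow the use of seed reserves, so its median cannot decide on reserve use itself. The written hypothesis asked for a median at or below -0.3 and took a median above -0.1 as against it. By that rule the median counts against the hypothesis for this set of genes. Its interval lay wholly above -0.3, and it stood at percentile 34.0 of random lists matched on FPKM, where the written hypothesis asked for a low one. The interval reaches below -0.1, however. Asking for the whole interval above -0.1, which the written hypothesis did not, decides neither way. Lipid-transfer superfamily and hydroxyproline-rich products were left out of the set of 36, a detail the written hypothesis did not state. With nothing left out, 115 genes had a median of -0.08 (interval -0.15 to -0.03), with the lipid-transfer superfamily alone left out 65 genes had -0.07, and with 2 further product terms 40 genes had -0.08. All 4 medians lay above -0.1 and all 4 intervals wholly above -0.3, with the medians at percentiles 25.5 to 34.0 of matched random lists. The fall that the hypothesis asked for was thus not met under any of the 4 definitions. Each interval reached below -0.1, so the stricter reading decided none of them.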
